A study of Mus musculus with 8 samples.

How the data were processed

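Gene expression was measured by RNA-seq in E14 mouse embryonic stem cells (a male line grown from the blastocyst), in unmodified (WT) cells and in cells in which Klf4 had been knocked out (KO), with 2 libraries per genotype that the labels call biological replicates. Contacts between genomic sites bound by RNA polymerase II were measured by HiChIP, which ligates chromatin ends that lie close together, pulls down 1 protein and sequences the joined ends as paired-end tags (PETs). The labels list 2 HiChIP samples per genotype, with fragments of 300 to 700 bp and reads of 150 bp.

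Per the submitters' processing notes, the series used mm10, HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1 and HiC-Pro 2.11.4. The deposited gene counts are whole numbers of reads per Ensembl gene and are not normalised. Their annotation release, strand setting and read filters are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart. The deposited loop files hold counts of PETs between pairs of anchors on 1 chromosome, with 1 file per genotype that its authors named as a mix of replicates. The loop caller, the peaks behind the anchors and the filters are not given in the sources used here. Because anchors were listed separately in each pool, sums over them move with how much was called.

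Gene counts summed to between 8287497 and 9762190 per library, or 34.5% to 36.0% of the records in each file. Reads in no gene made up 37.2% to 40.5%, reads with several alignments 17.5% to 18.9%, unaligned reads 1.97% to 2.94%, reads of low alignment quality 3.73% to 4.19% and reads shared between genes 0.959% to 1.43%. These records were left out of library sizes and tests. The WT columns carry replicate numbers that match the labels. The KO columns carry the letters B and F, so they were used as 2 libraries of the KO group without a number. Whether they come from 1 edited clone or from separate ones is not given in the sources used here.

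Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test, genotype as the only term), with Benjamini-Hochberg adjustment and a false discovery rate (FDR) threshold of 0.05. Of 52636 gene identifiers, 15517 passed the filter. The common biological coefficient of variation was 0.257, on 2 residual degrees of freedom and 6.29 prior ones. Symbols were taken from the supplied name table, which matched 52403 identifiers. Positions came from RefSeq on the same mouse build and matched 14139 tested genes. CPM denotes counts divided by the TMM-scaled library size, given as mean ± SD over the 2 libraries. Where a group had no count, the fold is a lower bound against 3 counts over the 2 libraries of that group, which equals 0.179 CPM in KO and 0.161 CPM in WT. Where a group had 1 to 3 counts, the ratio of summed counts is given with an exact conditional binomial 95% interval, which covers counting error and not the spread between libraries.

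Before the data were examined, 22 gene lists, the test of each comparison, the alternatives and the rule for naming genes had been fixed. Named genes are Klf4, Nanog, Pou5f1, Sox2, Klf2, Klf5, Esrrb, Sox1, Pax6 and Nes whatever their result. To these come the 10 higher and the 10 lower genes with the largest absolute log2 fold change among those past the FDR threshold, with a mean of at least 2 CPM and both KO libraries on the same side of both WT libraries, without predicted genes, Rik clones and pseudogenes. In each list, up to 4 members with the smallest p were added. Some genes are in more than 1 list, so the lists are not independent. Lef1 is in the formative and WNT lists, for instance, and Sp5 and Sp8 are in the WNT and KLF lists. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists. Measured members are those among the tested genes, and several lists lost many. Measured were 11 of 30 early neural ectoderm, 10 of 31 HOX and 7 of 20 mesendoderm genes. For the two-cell-like and the fibroblast and feeder lists they were 11 of 20 and 10 of 20. Alternatives for the expression results were RLE factors, library totals only, DESeq2 1.42.0, limma voom, other filters, leaving out each library, and for lists an estimated correlation and fry. With an estimated correlation, camera tests each list on the 2 residual degrees of freedom. A list can therefore lose its call in that setting without correlated genes. A fit on 2 libraries of 1 genotype and 1 of the other assumes that the lone library varies like the other group. In simulated counts of 15125 genes with the depths and means of these libraries, the edgeR test recovered 15 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, and called 4 unchanged genes. Changes were planted only in genes above a minimum expected count, with the trended spread for both genotypes. The real WT libraries differed more from each other than the KO libraries (chi-square per gene 60.6 and 27.2). Recovery and false calls in the real counts may therefore differ.

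In the loop files, a row that joins an anchor to itself was not taken as a loop. A loop is a pair of different anchors with at least 2 PETs. Loops were called shared when both anchors overlapped by at least 1 bp. The KO pool was thinned at random, without replacement, to the 35189 PETs of the WT pool in 100 draws, or 20 draws for overlaps and for gene classes. This equals total PETs only, since more KO PETs joined an anchor to itself, and keeps the KO anchors listed at full depth. The PETs between different anchors were therefore also thinned, to the 23586 of the WT pool. Shares carry exact binomial (Clopper-Pearson) and ratios of PETs exact conditional binomial 95% intervals, which cover counting error only, since PETs may include PCR copies and 1 pool per genotype shows no spread between replicates. The planned promoter window needed the strand, which the annotation used here does not give. Looped PETs of a gene were therefore summed over pairs with an anchor within 1 kb of either annotated end. Genes with at least 10 looped PETs over both pools were classed by a 2-fold difference in looped PETs, each divided by its pool's PETs between different anchors, which is also the scale of every KO to WT ratio of PETs. The difference in median log2 fold change between a class and the other such genes was tested with a two-sided permutation test over genes (100000 resamples), and changed genes in each class with Fisher's exact test. Named loops are the 5 with the most PETs in each pool, and, among all listed pairs of different anchors that match one to one, including those with 1 PET in a pool, the 5 with the highest and the 5 with the lowest KO to WT ratio at 20 or more PETs over both pools. The overlap code recovered all 300 of 300 planted loops. Alternatives were other PET minimums, spans of at least 20 kb, wider or half-overlapping anchors, thinned PETs, other gene windows and other fold changes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.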

Results

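The series compared WT E14 mouse embryonic stem cells with KLF4-KO cells by RNA-seq and by HiChIP for RNA polymerase II. Its title places KLF4, a zinc finger transcription factor of the naive pluripotency network, between chromatin folding and early neural differentiation. RNA-seq comprised 2 WT and 2 KO libraries, with 9020599 and 9762190 gene counts in the WT libraries and 8448519 and 8287497 in KO libraries B and F. Log CPM values correlated across genes at r = 0.96 between the WT libraries and r = 0.97 between the KO libraries, against 0.88 to 0.92 between genotypes. HiChIP was analysed as 1 pooled file per genotype, with 35189 PETs in WT and 401726 in KO. The labels give 2 media for the cells, the same for all 8 samples. Both hold 15% serum. One adds 10 ng/mL LIF with the MEK inhibitor PD0325901 (1 µM) and the GSK3 inhibitor CHIR99021 (3 µM), and the other 1000 U/mL LIF.

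Klf4 (ENSMUSG00000003032, chromosome 4, 55527137 to 55532475, mm10) had 2882 and 2421 counts in the WT libraries and 0 counts in both KO libraries. Its level was 284.8 ± 30.3 CPM in WT (SD, n = 2) and at least 1595-fold lower in KO, with an edgeR FDR of 1.9e-04. With no expression filter its edgeR FDR was 0.073.

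None of 6 core pluripotency genes other than Klf4 (Nanog, Pou5f1, Sox2, Klf2, Klf5 and Esrrb) passed the edgeR threshold. Nanog measured 779 ± 7.06 CPM in WT and 596 ± 34.3 in KO (SD, n = 2), a log2 fold change of -0.39 (95% interval -0.95 to 0.18, edgeR FDR 0.39). Pou5f1, which encodes OCT4, stood at 1604 ± 577 and 1652 ± 151 CPM (log2 fold change 0.04, edgeR FDR 0.95), and Sox2 at 499 ± 49.8 and 557 ± 7.72 CPM (0.16, edgeR FDR 0.74). The nuclear receptor gene Esrrb had a log2 fold change of -0.28 (edgeR FDR 0.54). Among the paralogs of Klf4, Klf2 had one of 0.12 (edgeR FDR 0.86) and Klf5 one of 0.28 (edgeR FDR 0.77). Klf5 lies on chromosome 14 and was called higher without WT replicate 1 (log2 fold change 1.15, edgeR FDR 0.019), but had a log2 fold change of -0.30 both without WT replicate 2 (edgeR FDR 0.68) and without KO library F (edgeR FDR 0.90). Klf2 and Pou5f1 also changed sign without WT replicate 1 and without KO library B, short of the threshold.

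Of the neural genes Sox1, Pax6 and Nes, the second rose, the last fell and Sox1 did not pass the edgeR threshold. Pax6, a regulator of eye and forebrain development, had 1 count in WT and 81 in KO, a 90.9-fold ratio (exact 95% interval 15.9 to 3630, for counting error only) at an edgeR FDR of 0.0097, and reached 4.83 ± 2.48 CPM in KO. Nes, which encodes the intermediate filament nestin of neural progenitors, fell 4.15-fold from 29.7 ± 3.23 to 7.15 ± 1.74 CPM (edgeR FDR 0.011). Sox1, an early neural plate marker, was at 6.39 ± 0.43 and 4.35 ± 0.29 CPM (edgeR FDR 0.45).

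Across all genes, edgeR called 1288 of 15517 at FDR 0.05, 460 higher and 828 lower in KO. At least 2-fold changes made up 453 of the higher and 818 of the lower calls. Since the clonal origin of the KO libraries is not given, these calls and the list tests below compare WT with KO libraries. They cannot separate the loss of Klf4 from other differences between the cells. Without WT replicate 1, 2517 genes passed, 1151 higher and 1366 lower. With no expression filter only 2 passed, against 4021 at an unadjusted p of 0.05.

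Besides Pax6, the 10 largest rises included genes of several kinds. Gap43, which encodes a protein of growing axons, had 2 counts in WT and 264 in KO, a 148-fold ratio (exact 95% interval 40.6 to 1230, which like the others here covers counting error and not the spread between libraries), at 15.7 ± 4.17 CPM in KO. Crmp1, for a protein of axon guidance, rose 56.3-fold to 49.2 ± 21.9 CPM, and Atcay, which encodes the brain protein caytaxin, 57.8-fold (exact interval 15.6 to 484) from 2 counts. Enpp2, the gene of the lysophosphatidic acid producing enzyme autotaxin, had no count in WT and was at least 30.7-fold higher in KO. Egr1, an immediate early gene, rose 50.7-fold to 14.3 ± 11.3 CPM, with 53 and 188 counts in KO libraries B and F. Lef1, a DNA-binding partner of beta-catenin, rose 30.5-fold to 26.7 ± 13.4 CPM, and Spn, a sialoglycoprotein gene of blood cells, 35.8-fold to 10.1 ± 3.12 CPM. Car4, a carbonic anhydrase gene, had 3 counts in WT and 201 in KO, a 75.2-fold ratio (exact interval 25.4 to 368), with 152 and 49 of the KO counts in libraries B and F. Aire, known for thymic antigen display, rose 50.3-fold to 152.1 ± 1.54 CPM. Its annotated span on chromosome 10 (78030022 to 78043610) overlaps that of Dnmt3l (78042287 to 78063622), so the assignment of its reads is uncertain. With Pax6, all 10 had an edgeR FDR between 1.9e-04 and 0.0097.

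Besides Klf4, the 10 largest falls included 4 Y-linked genes. Eif2s3y fell from 86.7 ± 4.35 CPM to 0 in both KO libraries, Ddx3y from 52.8 ± 21.7, Uba1y from 15.1 ± 11.9 and Uty from 14.2 ± 7.75, falls of at least 486-fold, 296-fold, 84.8-fold and 79.7-fold. Pramel6, of a multi-copy family active in early embryos, was at least 49.0-fold lower. Stk33, a kinase gene, was at least 47.2-fold lower and Serpina3m, of a clustered serpin family, at least 43.0-fold lower, and all 3 had no count in KO. Trpm1, a cation channel gene, fell 83.6-fold from 115.7 ± 2.82 CPM, and Bhmt, an enzyme gene of methionine synthesis, 80.3-fold from 39.3 ± 0.041 CPM. edgeR FDRs of these 9 genes lay between 1.9e-04 and 0.0080.

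**Figure D1:**
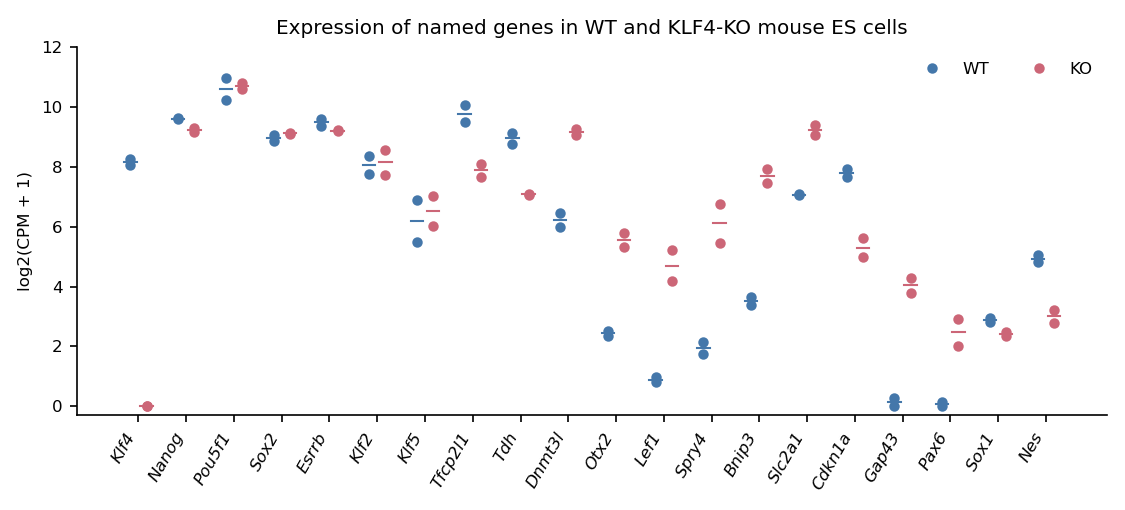
Expression of 20 named genes on a log2(CPM + 1) axis, with points for the 2 libraries of each genotype and lines for their means. Klf4 lies at 0 in both KO libraries, Nanog and Sox2 lie close together in both genotypes, and Otx2, Spry4 and Bnip3 lie higher in KO.

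Genes of the formative and primed epiblast, the state that follows naive pluripotency, were higher in 11 of 18 measured cases and lower in 1, and in 12 and 1 when adjusted over the list alone (camera adjusted p = 1.9e-12, adjusted p = 0.23 with an estimated correlation). Otx2, a regulator of that transition, rose 10.4-fold to 46.3 ± 10.6 CPM and lies on chromosome 14. Sox11 rose 13.7-fold, and Dnmt3a, a de novo DNA methyltransferase gene, 5.34-fold to 256 ± 50.7 CPM (edgeR FDR 0.0038 for both). General pluripotency genes rose in 6 of 18 cases, 8 adjusted over the list alone, and none fell (camera adjusted p = 6.4e-08, adjusted p = 0.25 with an estimated correlation). Among them were Dnmt3l (7.70-fold, to 575 ± 51.4 CPM), Lin28a, an RNA-binding repressor of let-7 (4.05-fold), and Utf1 (5.21-fold). Naive pluripotency genes fell in 6 of 20 cases with no rise, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.25 with an estimated correlation). Tfcp2l1, a naive pluripotency factor, fell 3.73-fold from 891 ± 241 CPM, Tdh, a threonine dehydrogenase gene on chromosome 14, 3.70-fold, and Jam2 3.16-fold. Spp1 fell 2.47-fold, a call lost without either KO library (edgeR FDR 0.27 and 0.085). Without KO library B the Jam2 call (edgeR FDR 0.12) and that of the naive list (camera adjusted p = 0.060) were lost.

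Targets of FGF-ERK signalling rose in 7 of 19 cases with no fall, 11 adjusted over the list alone (camera adjusted p = 2.1e-07, adjusted p = 0.25 with an estimated correlation). Feedback inhibitors were among them: Spry4 rose 25.7-fold to 74.9 ± 44.9 CPM and the phosphatase gene Dusp4 8.34-fold. Myc rose 12.2-fold from 2.05 ± 0.79 CPM. The list shares Etv4, Etv5, Myc, Fos and Ier3 with other lists. WNT-beta-catenin targets split, 3 higher and 4 lower of 15, also adjusted over the list alone (camera adjusted p = 0.51). Lef1 and Ccnd2 (23.7-fold) rose, whereas Cdx1 fell 29.6-fold from 53.3 ± 19.7 CPM and Sp5, an SP family factor, 18.3-fold. In the LIF-STAT3 list 3 of 19 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.10, and 0.045 without WT replicate 2 and 0.014 without KO library F). Besides Myc these were Ier3 (3.85-fold higher, edgeR FDR 0.098 without KO library B), Pim3 (2.02-fold higher) and Bcl3 (90.1 ± 22.9 to 42.9 ± 1.94 CPM). The Pim3 call was lost without WT replicate 1 or either KO library (edgeR FDR 0.056 to 0.36). The Bcl3 call was lost without WT replicate 2 or either KO library (0.10 to 0.29), and under other scalings, limma voom and other filters.

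Hypoxia and glycolysis genes had the smallest camera p of the 22 lists. Of 19 measured, 13 rose and 1 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 7.1e-16, adjusted p = 0.25 with an estimated correlation). Bnip3, a mitophagy receptor gene, rose 19.8-fold from 10.5 ± 1.39 to 209 ± 47.3 CPM. Pdk1, whose kinase inhibits the enzyme pyruvate dehydrogenase in mitochondria, rose 6.80-fold. The oxygen sensor gene Egln3 rose 5.92-fold and the glucose transporter gene Slc2a1 4.55-fold, to 605 ± 104 CPM. Mitochondrially encoded genes had a lower median (log2 fold change -0.72 over 11 genes) and the camera adjusted p was 0.0048 (adjusted p = 0.25 with an estimated correlation, and 0.060 for camera without KO library B). The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, which are not in that list and were picked after their values were seen, went the other way (log2 fold change 0.89 and 0.67, edgeR FDR 0.072 and 0.12). No single list member passed in edgeR (6 at an unadjusted p of 0.05) or limma voom, 3 were lower in DESeq2 and 5 adjusted over the list alone. mt-Cytb had 5150 ± 498 CPM in WT and 2392 ± 443 in KO (edgeR FDR 0.063, and 0.016 without WT replicate 2 and 0.049 without WT replicate 1).

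Targets of p53 fell in 8 of 19 cases with no rise, 9 adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.23 with an estimated correlation). Cdkn1a, the gene of the cell cycle inhibitor p21, fell 5.63-fold from 221 ± 28.7 to 39.3 ± 12.4 CPM. Phlda3 fell 3.60-fold, Btg2 3.19-fold and Plk2 3.00-fold, the last with an edgeR FDR of 0.064 without KO library B. Genes of the two-cell-like state, a rare cell state of stem cell cultures, fell in 8 of 11 cases, and in 11 adjusted over the list alone (camera adjusted p = 5.7e-10, adjusted p = 0.23 with an estimated correlation). Usp17la fell 9.02-fold, Usp17lc 8.46-fold, Usp17lb 5.88-fold and Gm8300 4.98-fold. These and the Zscan4 genes belong to multi-copy families, so counts of single members are uncertain.

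Imprinted and DNA methylation genes rose in 6 of 22 cases and fell in 1, 8 and 2 adjusted over the list alone (camera adjusted p = 8.4e-04, adjusted p = 0.41 with an estimated correlation). This list shares Dnmt3l and Zfp57 with the general pluripotency list, so the rise of Dnmt3l counts in both, and Peg10 with the trophoblast list. H19, an imprinted non-coding RNA gene, rose 10.7-fold and Mest 4.35-fold, whereas Plagl1 fell 38.2-fold from 36.8 ± 19.8 CPM. HOX genes fell in 4 of 10 cases, 5 adjusted over the list alone (camera adjusted p = 0.0025, adjusted p = 0.41 with an estimated correlation, and 0.096 for camera without WT replicate 2). The 4 were weakly expressed, from Hoxc4 at 6.06 ± 1.34 CPM in WT (5.60-fold lower) to Hoxd9 at 1.67 ± 0.71 CPM (at least 9.33-fold lower). Hoxc9 was at least 14.1-fold lower, and Hoxc10 8.38-fold lower, a call lost with DESeq2 (adjusted p = 0.093), under limma voom (adjusted p = 0.052) and without WT replicate 2 or either KO library (edgeR FDR 0.12 to 0.16).

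Neuronal genes showed rises in 5 of 14 and falls in 2, also adjusted over the list alone (camera adjusted p = 0.087, adjusted p = 0.71 with an estimated correlation). Gap43 and Ina (4.16-fold) rose, whereas the neurofilament genes Nefm and Nefl fell 14.5-fold and 8.97-fold. Both lie on chromosome 14. The list was past the camera threshold without WT replicate 2 (adjusted p = 0.045) and without KO library F (4.2e-04). Of 30 listed early neural ectoderm genes 11 were measured. These split evenly, 3 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.67, median -0.28). The Notch ligand gene Dll1 rose 15.1-fold to 23.7 ± 17.5 CPM, and Sox21, on chromosome 14, fell 7.55-fold.

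Marker lists of other lineages did not pass the camera threshold. Mesendoderm genes included Lefty2 (8.33-fold lower) and Gsc (14.2-fold lower, edgeR FDR 0.081 without WT replicate 2, limma voom adjusted p 0.052), with 2 of 7 lower, also adjusted over the list alone (camera adjusted p = 0.10, and 0.013 without KO library B). In the primitive endoderm list 4 of 13 rose and 3 fell, 4 and 4 adjusted over the list alone. Its median was 0.06, while camera pointed down (adjusted p = 0.95). The collagen chaperone gene Serpinh1 fell 3.96-fold, Sparc 2.97-fold (edgeR FDR 0.066 without KO library F) and Lama1 3.61-fold, whereas Lamb1 rose 2.94-fold. Of 14 trophoblast genes 3 rose and 2 fell, 3 and 4 adjusted over the list alone (camera adjusted p = 0.95). Peg10 rose 6.48-fold and Fgfr2 5.10-fold (edgeR FDR 0.15 without KO library B, limma voom adjusted p 0.052). Gata2 fell 4.89-fold, with an edgeR FDR of 0.057 without WT replicate 1 and 0.093 without KO library F. Germline genes had 1 rise and 2 falls of 18, 3 and 5 adjusted over the list alone (camera adjusted p = 0.92), with Mael 3.55-fold higher. None of 10 fibroblast and feeder genes passed in edgeR, over all genes or adjusted over the list alone (4 at an unadjusted p of 0.05, camera adjusted p = 0.68), none in limma voom and 1 in DESeq2. This was Fn1, at 2306 ± 760 and 1189 ± 229 CPM (edgeR FDR 0.12, and 0.0063 without WT replicate 2, DESeq2 adjusted p 0.035). Col5a1 was called lower without WT replicate 2 (edgeR FDR 0.033).

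The remaining lists held the factor's own family, genes of chromatin folding and the Hippo pathway. Apart from Klf4, 1 of 21 KLF and SP genes rose (Sp8, 9.99-fold, edgeR FDR 0.18 without KO library B, limma voom adjusted p 0.052) and 1 fell (Sp5), 2 and 3 adjusted over the list alone (camera adjusted p = 0.95). None of 22 genes of loop architecture passed in edgeR, over all genes or adjusted over the list alone, nor in DESeq2 or limma voom, and 1 had an unadjusted p under 0.05. Without WT replicate 1, however, Zfp281 (log2 fold change 1.57, edgeR FDR 0.0012), Pds5b (1.20, edgeR FDR 0.012) and Pds5a (0.98, edgeR FDR 0.031) were called higher. The list's median log2 fold change was 0.38 (camera adjusted p = 0.078, and 7.0e-04 without WT replicate 1 and 0.0039 without KO library B, and adjusted p = 0.78 with an estimated correlation). Zfp143 stood at 34 ± 4.15 CPM in WT and 47.8 ± 5.26 in KO (edgeR FDR 0.30). Hippo pathway genes fell in 3 of 22 cases, 5 adjusted over the list alone (camera adjusted p = 0.10, and 0.015 without WT replicate 2). The YAP target gene Ccn1 fell 4.76-fold, Amotl2 2.77-fold and Mob3c 3.07-fold, the last 2 with calls lost without KO library B (edgeR FDR 0.10 and 0.11). Mob3b (chromosome 4, 34949074 to 35157524) was at 11.5 ± 1.86 and 4.23 ± 0.72 CPM (edgeR FDR 0.058, and 0.038 without WT replicate 2, DESeq2 adjusted p 0.044).

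**Figure D2:**
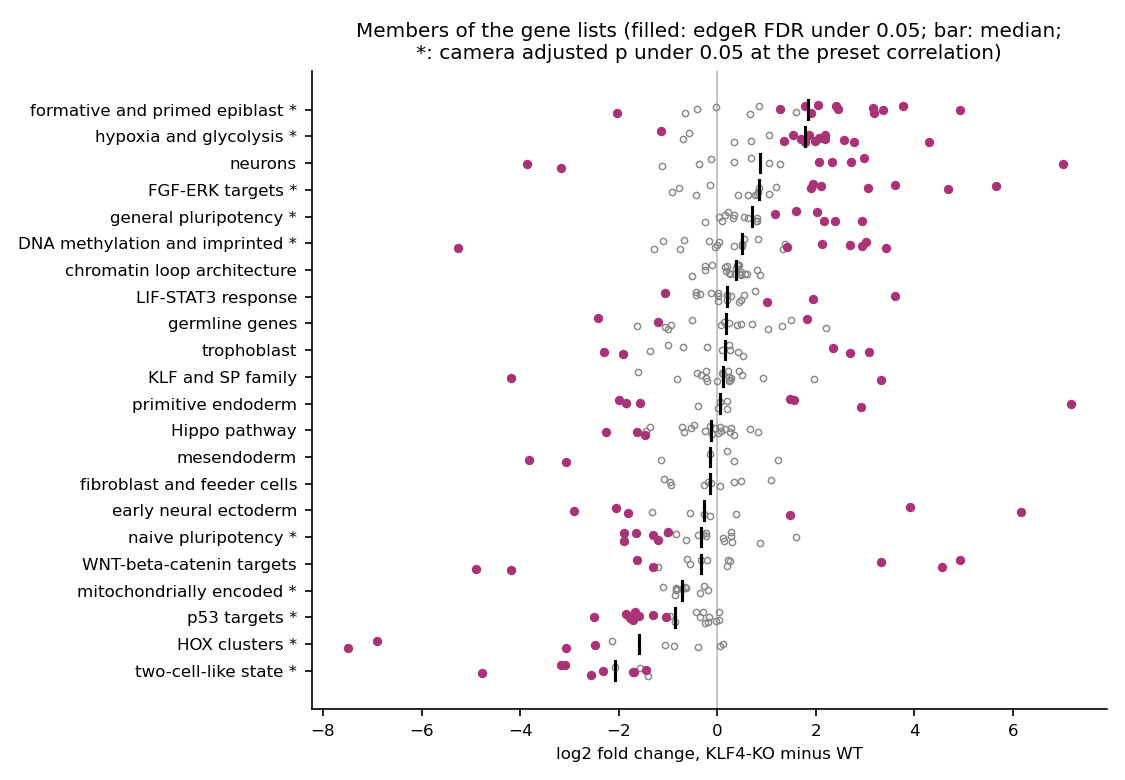
Log2 fold changes (KO minus WT) of the measured members of 22 gene lists, ordered by median. Filled points passed the edgeR FDR threshold, bars are medians, and asterisks mark the 10 lists past camera at the preset correlation. The 2 leftmost HOX genes had no count in KO, and 1 primitive endoderm gene had none in 1 genotype. The plotted values of these genes depend on the prior count.

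Expression differed between genotypes along stretches of chromosomes. All 7 Y-linked genes examined had 0 counts in both KO libraries, while Eif2s3y had 845 and 769 in WT. Zfy1 had 31 and 4 counts in WT. Kdm5d had 4 and 3 and Usp9y 4 and 4, so their 0 counts in KO carry little weight. Mid1-ps1, a pseudogene placed on the Y at 90753046 to 90765072 and not among the 7, stood at 22.7 ± 0.16 CPM in WT and 24.1 ± 4.44 in KO (log2 fold change 0.08, edgeR FDR 0.89). On chromosome 14 the median log2 fold change of 319 genes with at least 8 CPM was -0.66 (95% bootstrap interval -0.76 to -0.56), against -0.06 to 0.15 on the other autosomes. Both WT libraries lay above the gene means there, by medians of 0.36 and 0.28, and both KO libraries below, at -0.35 and -0.29. Of the 467 tested chromosome 14 genes 82 were called lower, 17.6% against 4.96% elsewhere (Fisher's exact odds ratio 4.08, p = 3.7e-22, across genes, which are not independent replicates). Against other autosomal genes, the median was -0.23 (-0.48 to 0.06) among the 107 genes nearest the start, -0.77 among the next 106 and -0.89 among the last 106. On chromosome 4, 50 of 52 genes between 10 and 40 Mb lay below the median of other autosomal genes, with a median of -0.84 (-0.95 to -0.65). That region was chosen after its values were seen, and holds Mob3b but not Klf4. Without the genes of chromosomes 14 and Y and of that region edgeR called 1137 genes, 428 higher and 709 lower.

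**Figure D3:**
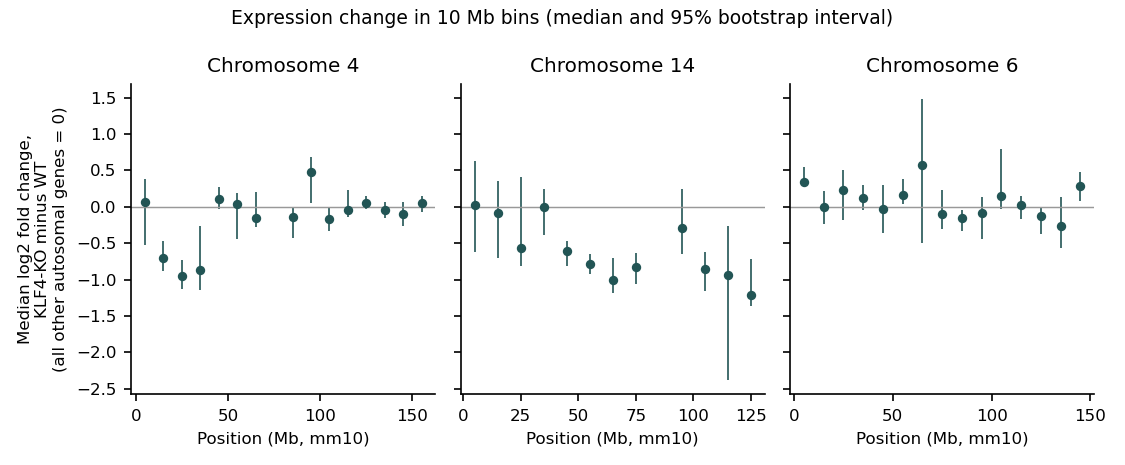
Median log2 fold change (KO minus WT, relative to the autosomal median) of genes with at least 8 CPM in bins of 10 Mb that hold at least 5 of them, along chromosomes 4, 14 and 6, with 95% bootstrap intervals. Bins between 10 and 40 Mb on chromosome 4 and most bins beyond 40 Mb on chromosome 14 lie below 0, and chromosome 6 is drawn for comparison.

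RNA polymerase II HiChIP listed more contacts in the KO than in the WT pool, with more PETs behind them. The WT pool held 3150 loops with at least 2 PETs, and the KO pool 30928, 9.82 times as many. Thinned to the 35189 PETs of the WT pool, the KO pool gave a median of 2505 loops (2401 to 2581 in 100 draws), 0.80 times the WT number, but held 20742 PETs between different anchors against 23586 in WT. Thinned to 23586 such PETs it gave 2951 loops (2874 to 3037 in 100 draws), 0.94 times the WT number. Both kinds of draw kept the KO anchors listed at full depth. Anchors numbered 8373 in WT and 18293 in KO, with median widths of 1999 and 2932 bp. As deposited, KO loops spanned more, with a median of 65.2 kb against 34.3 kb. Loops under 20 kb made up 35.9% in WT (exact 95% interval 34.2 to 37.6) and 22.3% in KO (21.8 to 22.8). After thinning the order turned, with a median span of 20.4 kb in KO (19.5 to 21.6), or 21 kb (19.9 to 22.2) with equal PETs between different anchors.

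**Figure D4:**
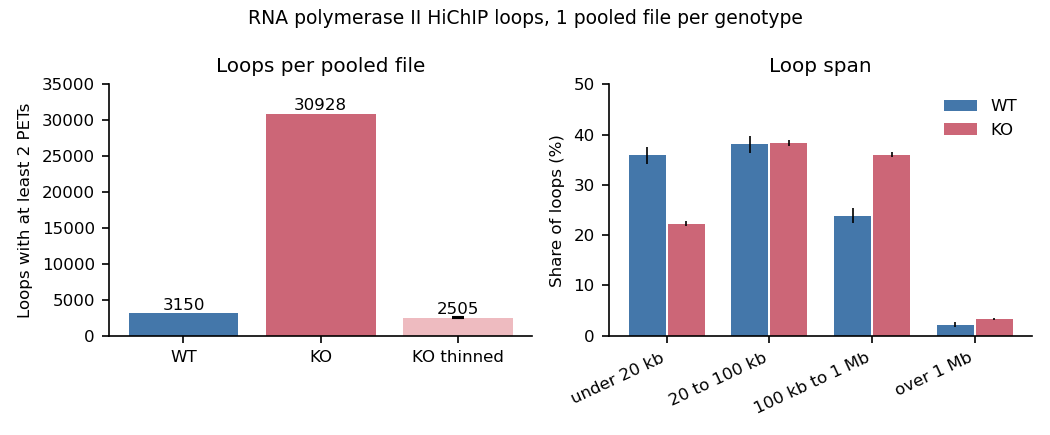
Left, loops with at least 2 PETs in the WT and KO pools and in the KO pool thinned to 35189 PETs (median, lowest and highest of 100 draws): 3150, 30928 and 2505. Right, share of loops by span in each deposited pool, with exact binomial 95% intervals that cover counting error only.

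Of the 3150 WT loops 1552, or 49.3% (exact 95% interval 47.5 to 51.0), had a counterpart among the KO loops. Both anchors overlapped KO anchors for 2284 WT loops, and 68.0% of these (66.0 to 69.9) were shared. Conversely, 4.58% of KO loops (4.34 to 4.81) were found in WT, a share limited by the smaller number of WT loops. Among loops of the KO pool thinned to the WT total of PETs it was 12.5% (median of 20 draws). With the KO pool thinned to the WT total of PETs, 12.2% of WT loops were shared (10.9 to 13.2 in 20 draws), and 13.5% (12.4 to 14.2) with equal PETs between different anchors. Separate draws of 35189 PETs from the KO pool alone shared 35.5% (34.7 to 36.4), which is the overlap between draws of 1 pool. Such draws use the same listed anchors, so this share is no baseline for the overlap between pools. With anchors extended by 5 kb the unthinned share was 70.4%.

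The strongest WT loop joined Malat1 and Neat1 on chromosome 19 (5794136 to 5804656 with 5841278 to 5850173, 47 PETs), neighbouring genes of abundant nuclear non-coding RNAs. Neat1 fell in expression (log2 fold change -1.49, edgeR FDR 0.011), and Malat1 had a log2 fold change of 0.16 (edgeR FDR 0.84). Of the next 4, 3 lay in the histone gene cluster of chromosome 13, between H1f2 and H3c3 (40 PETs), H3c3 and H2ac4 (39 PETs), and the H2ac8 and H4c4 groups (36 PETs). The remaining one joined unannotated sites on chromosome 8 (19783139 to 19785353 with 20120623 to 20122980, 37 PETs). The strongest KO loops lay at Ncor1 and Pigl on chromosome 11 (218 PETs), at Zfp57 and Mog on chromosome 17 (210 PETs) and within Zmynd8 on chromosome 2 (178 PETs). Next came a loop between Irf2bpl and a site without an annotated gene on chromosome 12 (176 PETs), and 1 at Tbc1d10b on chromosome 7 (175 PETs).

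Among all listed anchor pairs, including those with 1 PET in a pool, 257 that matched one to one had at least 20 PETs over both pools, with a median KO to WT ratio of depth-scaled PETs of 0.91. The highest ratios were within G3bp2 (96 PETs in KO, 1 in WT), between Bcl7b and Baz1b (91 and 1), at Cd9 (89 and 1), between Polr2e and Gpx4 (85 and 1) and within Etv5 (75 and 1). With 1 WT PET each the ratios were imprecise, as at G3bp2 with 9.56 (exact 95% interval 1.68 to 382) and Etv5 with 7.47 (1.30 to 299). The genes at named loops whose expression is given were chosen after their values were seen. Cd9, a tetraspanin gene, was lower (log2 fold change -1.31, edgeR FDR 0.020). G3bp2 had a log2 fold change of 1.34 (edgeR FDR 0.056) and Etv5 one of 0.80 (edgeR FDR 0.085). The lowest ratios were between the histone genes H4c11 and H4c12 (21 PETs in WT, 9 in KO, ratio 0.043, 0.017 to 0.097), at the splicing factor gene Srsf5 (19 and 10, ratio 0.052), at a second unannotated pair on chromosome 8 (21 and 13, ratio 0.062), between the H4c8 and H2ac8 groups (22 and 14, ratio 0.063) and at Rsrp1 (12 and 8, ratio 0.066).

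At the named genes, KO to WT ratios of depth-scaled PETs lay on both sides of 1. Their exact intervals cover counting error only, with 1 pool per genotype and anchors listed separately in each. Klf4 had 2 looped PETs in KO against 6 in WT, a ratio of 0.033 (exact 95% interval 0.0033 to 0.19). Nanog had 43 in WT and 244 in KO (ratio 0.565, 0.407 to 0.801), Sox2 14 and 56 (0.398, 0.219 to 0.775) and Pou5f1 9 and 181 (2.00, 1.03 to 4.45). Klf5 had 8 and 126 (1.57, 0.77 to 3.71), and Klf2 7 and 40 (0.57, 0.25 to 1.51). Egr1, which rose in expression, had 8 and 28 (0.349, 0.155 to 0.885). At the ends of Esrrb there were 4 and 0, but over the whole gene 67 and 441. Pramel6, which had no RNA count in KO, had 0 looped PETs in WT and 39 in KO. The exact 95% interval of its ratio started at 1.0, so a rise beyond depth was not clear. Sox1 had 0 and 2. No looped PET met the ends of the other 18 of the 28 named genes of the fixed and largest-change sets, Pax6, Nes, Gap43 and Lef1 among them. Over their whole bodies Aire had 3 looped PETs in WT and 31 in KO, Spn 8 and 0 and Gap43 0 and 4, and the rest had none.

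Expression was then set against the contacts at gene ends, the link that the series title raises. Of 14135 genes with a position, 7024 had at least 10 looped PETs over both pools. In 2398 the depth-scaled looped PETs were at least 2-fold higher in KO, and their median log2 fold change of -0.05 differed from that of the remaining genes by -0.086 (permutation p = 1e-05, the smallest the resamples can give, adjusted p = 1.5e-05). With classes from an exact test of the pools that difference was -0.047 (permutation p = 0.12). The 2409 genes with at least 2-fold fewer lay 0.050 above the remaining genes (permutation p = 0.0039, adjusted p = 0.0039), which was not past the threshold without WT replicate 1 (permutation p = 0.080) or without KO library B (permutation p = 0.13). It was 0.0029 with at least 20 PETs per gene (permutation p = 0.87) and 0.0050 by the exact test (permutation p = 0.77). Across genes, which are not independent replicates, Spearman's rho was -0.073 (permutation p = 1e-05). Genes called lower made up 5.80% of the class with more contacts against 2.72% of the others (139 genes, Fisher's exact odds ratio 2.20, adjusted p = 3.1e-09) and 2.24% of the class with fewer against 4.57% (odds ratio 0.48, adjusted p = 1.9e-06). Over all tested genes 828 of 15517 were called lower, a share near that of the class with more contacts. The excess is therefore one over the other looped genes only. At least 10 looped PETs were reached by 34.5% of changed genes and 51.1% of unchanged ones. Median expression was 46.3 CPM in genes with that many and 10.6 CPM in the rest. Genes called higher made up 2.17% and 2.03% of the 2 classes, against 2.18% and 2.25% of the others (Fisher's exact test, adjusted p = 1 and 0.73). Of the 2398 genes 1887 had no looped PET in WT. Fisher's exact tests were run on these unthinned classes only. Median expression also differed, at 35.6 CPM in the class with more contacts, 49.5 in that with fewer and 57.6 in genes within 2-fold. With the KO pool thinned to the WT total of PETs, the medians of both differences over 20 draws changed sign, to 0.026 (permutation p = 0.38) and -0.014 (permutation p = 0.52). Single draws had either sign, from -0.02 to 0.0671 and from -0.0627 to 0.0144. With equal PETs between different anchors the medians were 0.019 (permutation p = 0.50) and -0.015 (permutation p = 0.43).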

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

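The tests of loss of the Y, of a line with 2 X chromosomes, of fewer copies of all or part of chromosome 14 or part of chromosome 4, the bins of 10 Mb and the PETs in them were chosen only after the result was seen.

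PETs that join an anchor to itself, which are not counted as loops in the main comparisons, made up 41.05% of the PETs in the KO pool (exact 95% interval 40.9 to 41.2) and 32.97% in the WT pool (32.5 to 33.5). They stood out because the share in KO lay above that in the control pool by more than counting error, with 1 pool per genotype and no replicate check.

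Expression in KO was lower along parts of chromosomes 14 and 4 and at 7 Y-linked genes, of which Kdm5d and Usp9y had few counts in WT. A few strongly changed genes do not account for chromosome 14, since its genes short of the FDR threshold had a median of -0.5581 (-0.63 to -0.51) against other such genes. A lower dose of the whole chromosome is argued against by the bin from 30 to 40 Mb, whose 36 genes had a median of 0.002218 (-0.38 to 0.24), and KO cells with 2 X chromosomes by the X-linked median of 0.1613 (0.09 to 0.25). Loss of the Y (highest KO count of 7 genes 0) may account for these Y-linked genes. Mid1-ps1, a pseudogene of the X-linked Mid1 placed near the far end of the Y, was expressed in both genotypes (edgeR FDR 0.89). Reads shared with Mid1 were not tested, so this pseudogene cannot decide whether the whole chromosome was lost. Along chromosomes 14 and 4 the spread of medians of 10 Mb bins with at least 10 genes of at least 8 CPM was wider than with gene positions permuted (p = 0.0015 and p = 1e-04, the latter the smallest the permutations can give), as fewer copies of part of each in KO would give, whether as gain in WT or loss in KO cells; 10 of the 237 such bins in the genome lay below -0.5, all on chromosomes 4 and 14, against at most 4 in 1000 shuffles. HiChIP PETs in these bins did not settle this. In the 8 of these 10 bins with at least 20 WT PETs the median log2 ratio of KO to WT PET shares was 0.369, within the range of random sets of 8 other bins (95% between -0.588 and 0.63), and above -0.174, the upper end of that range after a drop as large as that of expression in these bins (-0.804). Over anchors of both pools it was -0.157, also above that bound (-0.378), but over pairs of such anchors it was -0.557 in 5 bins, which is within the range of random sets (-0.866 to 0.507) and below the bound (-0.275). Since the PET sets disagree, fewer copies of parts of chromosomes 4 and 14 and regional control by KLF4, which was not tested, cannot be told apart.

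More loops in the KO pool went with depth. Thinned to equal total PETs, which left 20742 PETs between different anchors in KO against 23586 in WT, the KO to WT ratio of loops was 0.7952 (0.76 to 0.82 over 100 draws). With equal PETs between different anchors it was 0.937 (0.91 to 0.96), so PET depth may account for the 9.82-fold excess. Between anchors that overlap an anchor of the other pool there were 2383 loops in WT and 7291 in KO before thinning. Thinned to equal PETs between these anchors, the ratio was 1.059 (1.02 to 1.08). Anchors and depth both changed in that comparison, so a difference in the listed anchors remains a candidate explanation for part of the excess. A genotype effect on the number of contacts stays untested, since each genotype has 1 pool.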

How the results depend on the processing

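Alternatives that used anchors of both pools only, an exact test of the 2 pools, the whole gene body, self-joined anchors, equal PETs between different anchors or fewer chromosome regions were chosen after the data were seen. Where no cause is given, the cause was not tested. No filter on low counts left edgeR with 2 changed genes, 1 higher and 1 lower, both at least 2-fold. Klf4 was then at a log2 fold change of -14.3 with an FDR of 0.073. Since Klf4 had no count in KO, its edgeR fold changes, also without 1 library, depend on the prior count. Their narrow range shows no stability. The log2 fold change of Klf4 was -13.7 in DESeq2 and -12.2 in limma voom, and its bound is at least 1595-fold. Without 1 library at a time, changed genes numbered 1013 to 2517, those higher 387 to 1151, those lower 618 to 1366, those at least 2-fold higher 387 to 1055 and at least 2-fold lower 618 to 1244, with the upper ends without WT replicate 1. Klf4 ran from -14.41 to -14.16 and lists past camera from 10 to 12. Other scalings, tests and filters gave 1132 to 1644 changed genes. An estimated correlation left 0 lists past the threshold (lowest adjusted p 0.23, 4 at an unadjusted p of 0.05), and fry 3 in one direction (formative, two-cell-like and p53) and 21 in either. The former setting rests on 2 residual degrees of freedom. The estimates were below the preset 0.01 for the formative (-0.058), two-cell-like (-0.088), naive, p53 and mitochondrial lists, so correlated genes do not explain their loss. They were above it for the general pluripotency, FGF-ERK, HOX, hypoxia (0.26) and imprinted lists. Among values for single genes and lists under these alternatives, 1072 kept direction and side of the threshold, 16 turned direction short of the threshold in both settings, 133 kept direction but lost the call (79 of them without a filter) and 35 gained it. Without 3 chromosome regions, picked because their genes were lower in KO, 13 lists passed camera, the neuronal list among them, which loses its falling members Nefm and Nefl by that choice. The KO to WT ratio of loops was 6.48 for all listed pairs, 19.4 for at least 5 PETs, 0.795 thinned to equal total PETs, 0.937 thinned to equal PETs between different anchors and 1.06 between anchors of both pools, thinned. The share of WT loops found in KO was 32.4% for all pairs, 52.8% for at least 3 PETs, 70.4% with extended anchors and 12.2% thinned, or 13.5% with equal PETs between different anchors, where fewer KO PETs explain the drop by construction. For genes with more looped PETs in KO, the median difference was 0.026 thinned (-0.02 to 0.0671 over 20 draws) and 0.019 with equal PETs between different anchors, both reversed in the median only. It was -0.047 by the exact test of the pools (permutation p = 0.12), and ran from -0.097 to -0.074 without 1 library. For genes with fewer it was -0.014 thinned (-0.0627 to 0.0144 over 20 draws) and -0.015 with equal PETs between different anchors, both reversed in the median only. It was 0.0029 with at least 20 PETs (permutation p = 0.87) and 0.00504 by the exact test (permutation p = 0.77), and ran from 0.026 to 0.068 without 1 library. The call was lost without WT replicate 1 (permutation p = 0.080) and without KO library B (0.13). No paired analysis was possible because the KO count columns carry letters, not replicate numbers; the replicate block was not run. Depth limits the WT pool most, where 80.5% of anchor pairs had 1 PET.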

Other observations

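The test of the growth medium by WNT-beta-catenin targets and the bins of 10 Mb were chosen after the result was seen. Of the FGF-ERK targets 7 of 19 passed the edgeR threshold as higher in KO and none as lower, and of the formative genes 11 of 18 as higher and 1 as lower. Neither list passed camera with an estimated correlation (adjusted p = 0.25 and 0.23). Both media in the labels cover all samples, 1 with and 1 without inhibitors of MEK and GSK3. A candidate explanation is that KO cells were grown without the inhibitors, which would also lower WNT-beta-catenin targets. Their median log2 fold change was -0.3365 (95% bootstrap interval -1.21 to 0.22), with Cdx1, Sp5, Tnfrsf19 and Axin2 lower and Lef1, Ccnd2 and Sp8 higher, so the growth medium and the loss of KLF4 cannot be told apart. Tnfrsf19 and Axin2 were named after their values were seen.

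Xist had 244 and 150 counts in the WT libraries and 134 and 246 in KO (log2 fold change 0.10, edgeR FDR 0.90). PETs on chromosome Y numbered 91 in WT and 58 in KO, from pools of 35189 and 401726 PETs, so their share was smaller in KO. The first anchor started at 90718377 in WT and 90716886 in KO, far from the 4 Y-linked genes named above. Among bins of 10 Mb with at least 10 genes of at least 8 CPM, the only one with a median above 0.5 lay on chromosome 19, between 30 and 40 Mb (0.66, 0.26 to 0.87, 24 genes).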
